A study of Mus musculus with 6 samples.

How the data were processed

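6 libraries of poly(A)-selected mouse liver RNA were sequenced, 3 from mice given water and 3 from mice given the ethyl acetate fraction of a Chebulae Fructus extract. Groups and replicate numbers were taken from the labels. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the genome build GRCm38 are listed per the submitters' processing notes, which give no roles or settings. The deposited table held 1 value per gene and library, to 2 decimals, under headers that name no unit.

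The deposited values were taken as FPKM, made by the authors before deposit, because of their sums. Multiplied by the length of each gene's longest transcript, they came to between 110.5% and 111.9% of a library's fragments in every library, while the plain sums ranged from 517984 to 583245; TPM values would sum to the same total. FPKM removes library size, so a few very abundant liver transcripts can shift all other values, and it divides reads among similar genes by estimation. Read totals could not be recovered. Sparse low values had a modal ratio of 1 in most library pairs, which the 2 decimals make too coarse to give relative depth. Depth and counting error are therefore unknown.

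The table had 22899 rows, of which 5161 were blank in all libraries and 592 of the other 17738 were at 0 in all. 11 symbols that a spreadsheet had turned into dates were restored through the gene ID. 21633 gene IDs matched the RefSeq annotation of GRCm38.p6, the source of coordinates. Group mean columns made by the authors were not used in tests.

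The main comparison was planned before the data were examined, with a count-based test if counts were given and otherwise limma on log2(FPKM + 1). As FPKM were found, the second was used: limma 3.58.1 in R 4.3.3, with a trended prior variance, on 10282 genes with at least 1 FPKM in at least 3 libraries. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. No pairing or batch term was included, since the labels state none.

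44 gene lists (pathways, liver zones and cell types) were fixed in advance and tested with camera, with a preset correlation of 0.01 between genes, where at least 5 members were tested. The same lists were tested with an estimated correlation and with fry, whose main p tests whether members move one way on balance without comparing them with other genes. Counts per list are given over all genes and adjusted over the list alone. Several lists share genes, so their results are not independent. Single values were compared with a two-sided exact permutation test over the 20 assignments of 3 and 3 libraries, whose smallest p is 0.1.

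Named genes followed a rule set in advance. As fewer than 20 genes passed, the 10 per direction with the smallest p were named, provided that their groups did not overlap, their mean was at least 1 FPKM and their symbol was not a predicted gene. To these came up to 4 members with the smallest p of each called list or list with a called member, and 14 genes chosen whatever their result, of which 12 are reported here. Other genes named in the closing section were chosen after their values were seen.

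The gene and list tests were tested on simulated data with each gene's own mean and its spread as moderated by limma. There were 10282 genes and 200 changed ones, in 20 runs. Of genes changed by 1 on the log2 scale 90.1% were recovered, and of those changed by 2, 99%, with 5.4% false calls. With no change, 0.2 genes and 0.05 lists were called per run on average. Those simulated genes varied independently of each other, unlike genes in tissue. No simulated library stood apart as a whole. Moderated spreads differ less between genes than measured ones, and 200 changed genes make the adjusted threshold easier to reach, so both settings can favour recovery. The rates may therefore not hold for these libraries. In the real data Hectd2, with a log2 fold change of 1.01, had a limma adjusted p of 0.0792. Other divisions of the real libraries into 3 and 3 called 8 to 17 lists.

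Alternatives covered scaling, filters, the pseudocount, thresholds, variance options, a replicate block, library weights and leaving out each library. Methods that need read counts were not run.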

Results

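Liver gene expression was compared between mice of the outbred ICR stock that received a fruit extract and mice that received water. The extract was the ethyl acetate fraction of a water-soluble preparation of Chebulae Fructus, the dried fruit of Terminalia chebula used in traditional Asian medicine. It was given by gavage at 1 g/kg per day for 1 week, and the water group received 10 ml/kg for 1 week. Each group held 3 liver libraries, here called water 1 to 3 and extract 1 to 3. The labels give no sex, cage or day of sampling, and do not state outright that each library came from a separate animal, so p-values measure the spread between these libraries. The unit is not named in the table and was inferred from the values as FPKM, fragments per kilobase of transcript scaled to library size. The FPKM values of a library summed to between 517984 and 583245, and 15440 to 15601 genes had a value above 0. Total read numbers were not given, so the counting error behind a single FPKM value is unknown. Of the 17738 genes with values, 10282 reached 1 FPKM in at least 3 libraries and were tested.

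The comparison asked which liver transcripts differed after a week of extract. 5 genes passed limma's test at the Benjamini-Hochberg threshold, 2 higher and 3 lower in the extract livers. Hsd3b2, which encodes a hydroxysteroid dehydrogenase of steroid metabolism, rose from 16 ± 2.25 to 72.3 ± 16.3 FPKM (mean ± SD, n = 3 per group throughout), a log2 fold change of 2.09 with a standard error of 0.19 (limma adjusted p = 0.0392). Adh4, an alcohol dehydrogenase that also acts on retinol, rose from 33.3 ± 5.72 to 80.6 ± 1.48 FPKM (log2 fold change 1.26, limma adjusted p = 0.0492). Mt2, a metallothionein that binds zinc and copper, fell from 806 ± 144 to 206 ± 37.8 FPKM (log2 fold change -1.96, limma adjusted p = 0.0392). Cyp4a10, a fatty acid hydroxylase and a target of the nuclear receptor PPARα, fell from 769 ± 88.0 to 291 ± 37.6 FPKM (log2 fold change -1.4, limma adjusted p = 0.0492). Tm7sf2, a sterol reductase of cholesterol synthesis, fell from 137 ± 17.5 to 60.2 ± 2.49 FPKM (log2 fold change -1.17, limma adjusted p = 0.0492). For each of the 5, all extract libraries lay on one side of all water libraries.

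On GRCm38, Hsd3b2 (gene ID 15493) lies on chromosome 3 from 98711107 to 98724543 and Adh4 (26876) on chromosome 3 from 138415456 to 138432683. Mt2 (17750) lies on chromosome 8 from 94172618 to 94173567, Cyp4a10 (13117) on chromosome 4 from 115518287 to 115533649, and Tm7sf2 (73166) on chromosome 19 from 6062821 to 6067850. Hsd3b2 and Cyp4a10 belong to clusters of similar genes, so their levels are uncertain where reads could be divided among copies. Without limma's multiple-testing correction, 1061 genes had p below 0.05 (668 higher, 393 lower), against 514 expected on average if no gene differed. Other divisions of the libraries into 3 and 3 gave between 141 and 1060 such genes. The 1060 came from exchanging water 1 and extract 3, though only 1 gene then passed the threshold. The numbers higher and lower in the real comparison depended on scaling: after centring each library on its median gene they were 493 and 568. All 5 calls were lost when any library other than extract 3 was left out. By limma 0 genes passed without water 1, water 2, extract 1 or extract 2 (1580, 735, 729 and 733 at unadjusted p below 0.05) and 1, Cyp17a1, without water 3. Without extract 3, 48 genes passed (40 higher, 8 lower), these 5 among them. Extract 3 lay nearest to the water libraries on the first principal component (2.06, against 14.2 and 26.8 for the other extract libraries and -23.1 to -3.81 for water), and water 1 stood apart on the second (29.6, against -11.9 to -2.74 for the other libraries) and nearer to extract 3 on the first than to the other water libraries. The values leave open whether either library had the treatment its label states, and for extract 3 they differed between gene lists. Its fatty acid oxidation score (mean log2(FPKM + 1) of the list's members) was 5.76, the lowest of all libraries, against 6.18 to 6.58 in water. Its Kupffer score was 3.93, against 3.24 to 3.58 in water, while its interferon score was 2.84, against 2.57 to 2.78. These lists were called with extract 3 included. 2 genes (1 higher, 1 lower) passed after quantile normalization, 4 (1 higher, 3 lower) after upper-quartile scaling or rescaling to a common sum, and 0 after median centring or median-of-ratios scaling (1061 and 1044 genes at limma's unadjusted p below 0.05).

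**Figure D1:**
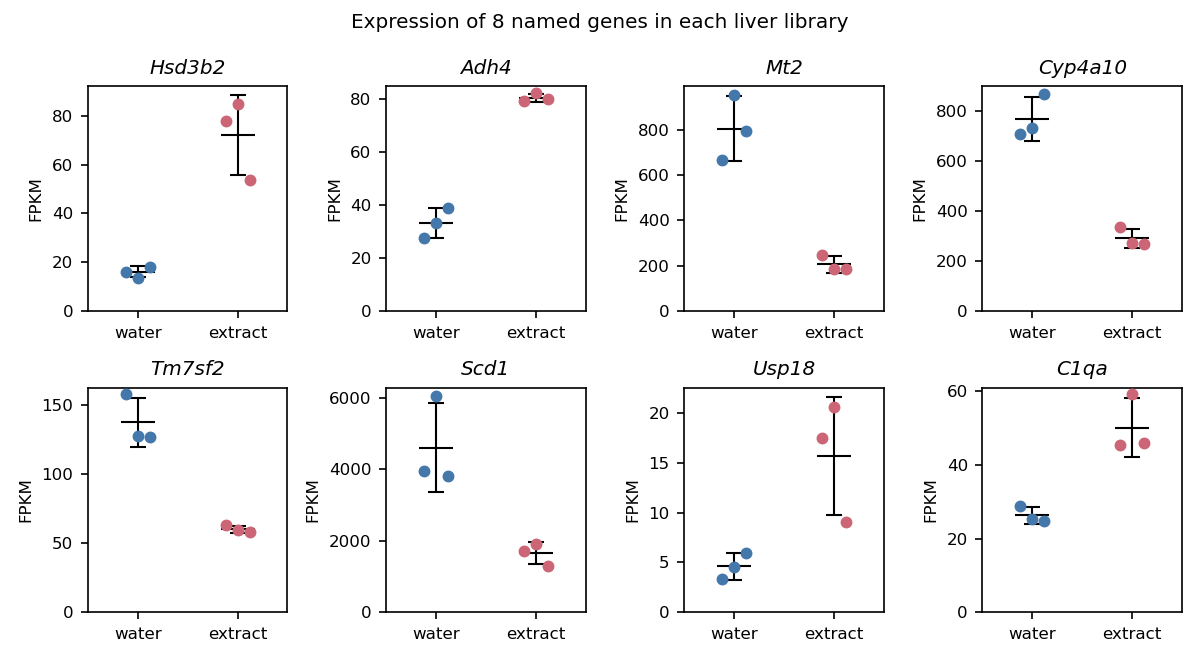
FPKM of 8 named genes in the 3 water and 3 extract libraries; points are libraries, long horizontal marks are means and error bars are SD. The groups do not overlap for Hsd3b2, Adh4, Mt2 (806 against 206 FPKM), Cyp4a10 and Tm7sf2, which passed the threshold, nor for Scd1, Usp18 and C1qa, which did not pass it.

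The genes with the next smallest p-values did not pass the threshold, with limma adjusted p between 0.0792 and 0.0882. Higher in all extract libraries than in all water libraries were Hsd3b5 (2.76 ± 0.55 against 60.0 ± 44.5 FPKM), Serpina11 (95.8 ± 0.54 against 181 ± 15.3), Ptgds (3.34 ± 0.48 against 12 ± 3.54), Ugt2b35 (28.9 ± 1.4 against 70.2 ± 17.7), Hectd2, Csrnp1, Svil and Atp8b1. Lower in all extract libraries were Mt1 (1214 ± 330 against 273 ± 97.5 FPKM), Acot1 (37.1 ± 11.5 against 11.4 ± 1.22), Cyp4a14 (718 ± 68.7 against 361 ± 26.2), Ugt1a5 (65.8 ± 16.2 against 18.6 ± 6.44), Ropn1l, Nrg4 and Klk1b4. Mt1 lies beside Mt2 on chromosome 8 and Cyp4a14 beside Cyp4a10 on chromosome 4. Of the 10282 genes, 1638 (15.9%) had no overlap between the groups, where chance gives 10%.

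Of 44 gene lists fixed before the data were examined, 38 had enough tested members. Camera with a preset correlation of 0.01 between genes called 19 of them, 9 higher and 10 lower. None of the 19 calls held with an estimated correlation, where their adjusted p lay between 0.396 and 0.60, and none held in fry's directional test (3 and 7 of the 38 lists at unadjusted p below 0.05). Fry's test for change in either direction passed for 21 lists, 14 of them among the 19. Each list score, the mean log2(FPKM + 1) of a list's members in a library, was also compared between groups. The scores did not overlap for 9 of the 38 lists, where chance gives 3.8 and another division of the libraries gave 7, and the exact permutation p for these was 0.1, the smallest that 3 against 3 libraries allow.

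**Figure D2:**
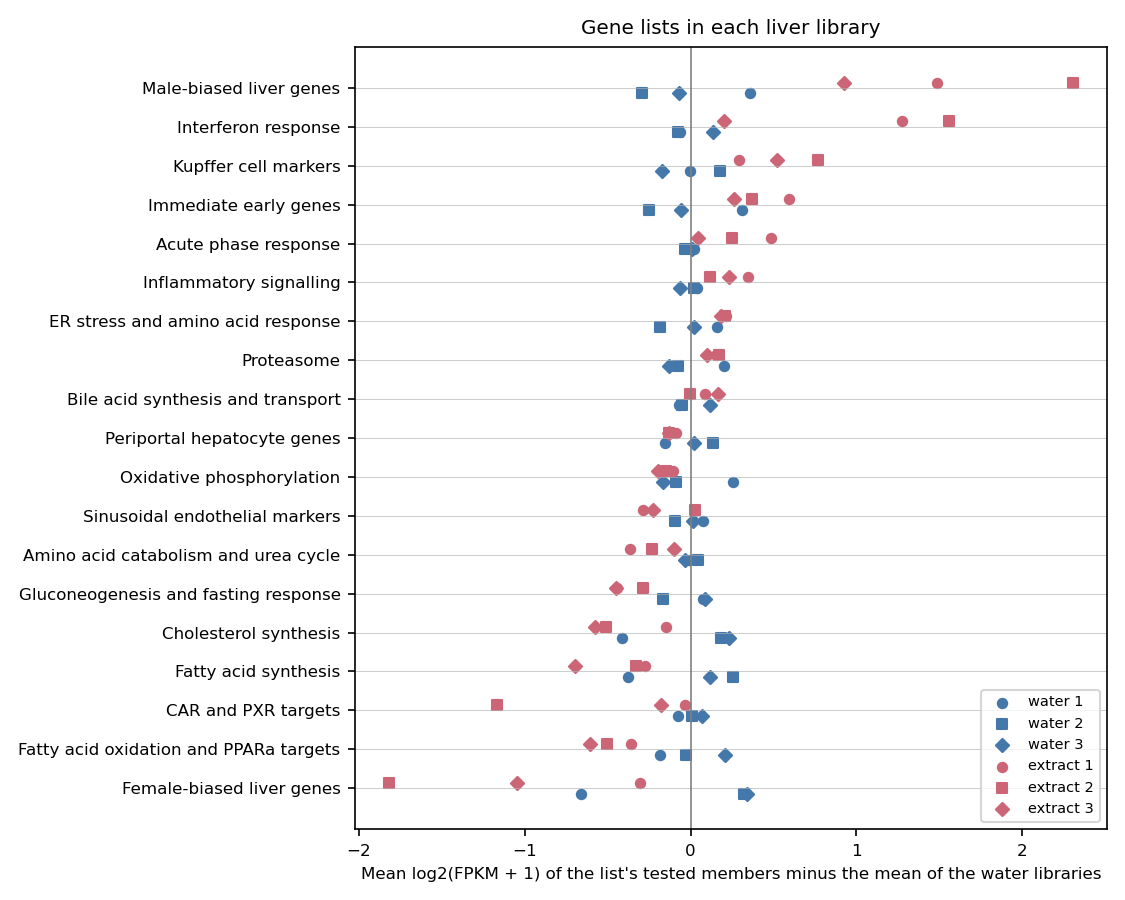
Score of each of the 19 called lists in each library, as the mean log2(FPKM + 1) of its tested members minus the mean of the 3 water libraries. Male-biased and interferon genes had the highest extract scores, with extract 3 near the water libraries for the interferon list (2.84 against at most 2.78 before subtraction).

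Interferon-response genes, the antiviral and immune genes induced by interferons, were called higher as a list in the extract livers. All 39 tested members had a positive log2 fold change, with a median of 0.97 (camera adjusted p = 1.18e-19), while the adjusted p was 0.396 with an estimated correlation. The list also did not pass fry's test for change in either direction (fry adjusted p = 0.0797), which 21 of the 38 tested lists passed. No member passed limma over all genes tested (30 at unadjusted p below 0.05), and 22 passed when adjusted over the list alone. Ddx58, a sensor of viral RNA, had 4.02 ± 0.64 FPKM in water and 8.90 ± 1.42 in extract livers. Usp18, which removes the ubiquitin-like protein ISG15 from its targets, had 4.62 ± 1.33 and 15.7 ± 5.93, Ifi47 had 3.69 ± 0.75 and 9.13 ± 3.00, and Xaf1 had 2.58 ± 0.37 and 7.74 ± 3.25. The list score was 2.58, 2.57 and 2.78 in the water libraries and 3.92, 4.20 and 2.84 in the extract libraries, so extract 3 lay just above water. Kupffer cell markers were higher in the same comparison (median log2 fold change 0.56). Adjusted over the list alone, 37 members passed without extract 3, 3 without extract 2, and 1 without any one of water 1, water 2 or extract 1; it was 13 after median centring, quantile normalization or median-of-ratios scaling, with a robust prior, or with either other filter on low genes, and 37 with library weights.

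**Figure D3:**
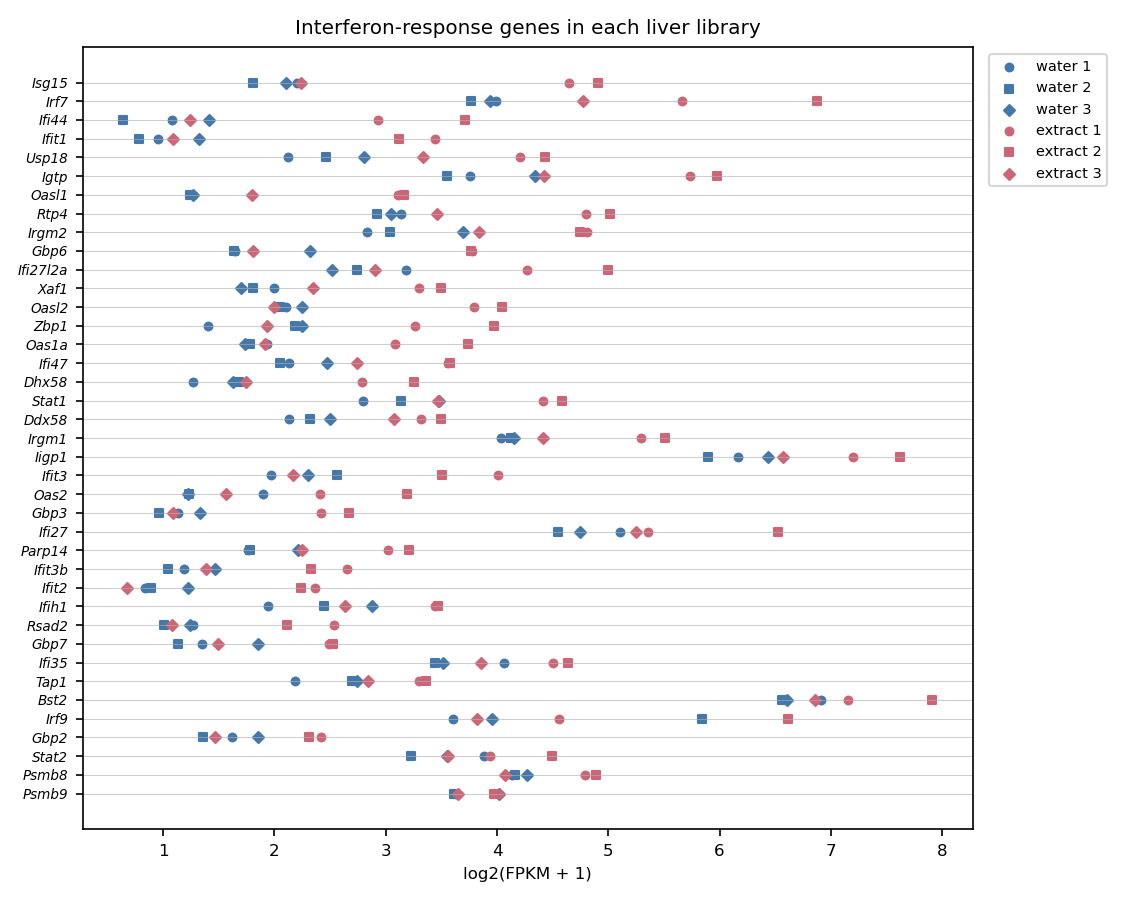
Log2(FPKM + 1) of the 39 tested interferon-response genes in each library, one gene per line. Extract 1 and extract 2 lie to the right for most genes, while extract 3 lies close to the water libraries; the median log2 fold change over the 39 genes was 0.97.

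Genes with higher expression in male than in female mouse liver were called higher as a list, and genes with higher expression in female liver lower. Of 21 tested male-biased genes, 20 had a positive fold change, with a median log2 of 1.18 (camera adjusted p = 7.15e-13; adjusted p = 0.396 with an estimated correlation), and 15 passed when adjusted over the list alone (5 with a robust prior). None passed limma over all genes (16 at unadjusted p below 0.05). C8a, a complement component, had 93.5 ± 8.27 FPKM in water and 167 ± 24.2 in extract livers, Nudt7 had 75.9 ± 16.6 and 218 ± 78.5, and the repressor Bcl6 had 2.31 ± 0.42 and 5.25 ± 1.70. Of 25 female-biased genes, 22 had a negative fold change, with a median of -0.73 (camera adjusted p = 6.64e-10; adjusted p = 0.396 with an estimated correlation). Cyp4a10 passed over all genes, and 4 passed when adjusted over the list alone. Cyp17a1, a steroid hydroxylase, had 17.7 ± 14.4 FPKM in water and 0.83 ± 0.26 in extract livers, Fmo2 had 22.5 ± 2.14 and 13.5 ± 1.31, and Cyp2a4 had 318 ± 144 and 59.9 ± 77.7. The male-biased list holds major urinary protein genes, near-identical copies whose single values are uncertain, and the other list holds copies of the Cyp2b, Cyp3a and Sult2a families. Mup7, of the male-biased list, had 0.27 ± 0.47 FPKM in water and 42.5 ± 52.9 in extract livers. It reached 1 FPKM only in the extract libraries, so it was tested only because it was higher there. With no filter on low genes the male-biased median was 0.89. Y-linked transcripts were present in every library, with a sum over 4 genes of 25.1 to 38.8 FPKM. The female-biased median was -1.36 without water 1, -1.14 without extract 1, -1.12 with a pseudocount of 0.01 and -1.11 with a filter at a mean of 5 FPKM, and 2 genes passed over the list alone without water 2, after median centring, quantile, median-of-ratios or upper-quartile scaling, with no filter or with a robust prior.

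Genes of fatty acid oxidation and other PPARα targets were called lower as a list. Of 48 members 44 had a negative fold change, with a median log2 of -0.42 (camera adjusted p = 1.18e-19; adjusted p = 0.396 with an estimated correlation). Cyp4a10 passed over all genes, and 14 members passed when adjusted over the list alone. Besides Acot1 and Cyp4a14, Crat, a carnitine acetyltransferase, had 34.0 ± 3.42 FPKM in water and 19.1 ± 1.45 in extract livers. The count over the list alone was 7 without water 2 or water 3 and 8 without extract 2, and the median was -0.24 without extract 3 and -0.27 with a filter at a mean of 5 FPKM or with library weights.

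Both lists of lipid synthesis genes were called lower. For cholesterol synthesis, 24 of 26 members had a negative fold change, with a median of -0.44 (camera adjusted p = 3.26e-10; adjusted p = 0.396 with an estimated correlation). Tm7sf2 passed over all genes, and 4 members passed when adjusted over the list alone, among them Pmvk (35.0 ± 3.35 against 20.6 ± 2.42 FPKM), Fdps (101 ± 15.9 against 49.7 ± 13.3) and Ebp (119 ± 11.5 against 87.1 ± 6.44). For fatty acid synthesis, 19 of 23 members had a negative fold change, with a median of -0.35 (camera adjusted p = 4.97e-08; adjusted p = 0.396 with an estimated correlation). None passed limma over all genes (7 at unadjusted p below 0.05) and 4 passed when adjusted over the list alone: Scd1, the stearoyl-CoA desaturase (4600 ± 1251 against 1648 ± 309 FPKM), the desaturase Fads1 (218 ± 31.1 against 119 ± 13.9), Acss2 (69.4 ± 16.8 against 36.5 ± 2.94) and the acetyl-CoA carboxylase Acacb (15.3 ± 5.81 against 6.28 ± 1.58). Water 1 had the lowest water score in both lists, and the scores of the groups overlapped. Without water 1 the counts over the list alone were 13 for cholesterol and 11 for fatty acid synthesis, without water 2 the cholesterol count was 2, and without water 3 the cholesterol median was -0.25. With library weights the counts were 9 and 12.

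Markers of Kupffer cells, the resident macrophages of the liver, were called higher as a list. Of 14 members 13 had a positive fold change, with a median of 0.56 (camera adjusted p = 9.84e-09; adjusted p = 0.396 with an estimated correlation), and 7 passed when adjusted over the list alone. None passed limma over all genes (9 at unadjusted p below 0.05). The complement genes C1qa (26.4 ± 2.23 against 50.2 ± 7.89 FPKM) and C1qb (24.2 ± 1.60 against 41.7 ± 11), Cd68 (6.85 ± 0.79 against 12.4 ± 2.72) and Clec4f (19.2 ± 2.71 against 30.0 ± 4.77) were among them. Sinusoidal endothelial markers were called lower as a list, with 13 of 14 fold changes negative and a median of -0.17 (camera adjusted p = 0.00222; adjusted p = 0.515 with an estimated correlation), and 0 passed by limma over all genes or over the list alone (1 at unadjusted p below 0.05). That gene was Fcgr2b, at 33.3 ± 1.0 against 26.4 ± 3.14 FPKM, while Gpr182, Stab2 and Stab1 had log2 fold changes between -0.33 and -0.22. Hepatocyte markers were not called (median 0.15, camera adjusted p = 0.853). A haemoglobin sum that left out Hbb-b1 made up 0.323% ± 0.189 of the FPKM sum in water and 0.112% ± 0.0218 in extract livers (exact permutation p = 0.1). It is therefore not total haemoglobin. Hbb-b1 itself had 450 ± 110 FPKM in water and 247 ± 78.9 in extract livers. Albumin made up 12.2% ± 1.46 and 9.17% ± 1.49 (exact permutation p = 0.2). Without water 3, 1 Kupffer marker passed over the list alone. The endothelial median was -0.10 without extract 1 and -0.26 without extract 2.

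Acute phase genes, secreted by hepatocytes in inflammation, were called higher as a list, with 27 of 33 fold changes positive and a median of 0.43 (camera adjusted p = 9.49e-04; adjusted p = 0.396 with an estimated correlation). Over all genes only Mt2 passed, and it fell. Adjusted over the list alone, 8 members were higher and Mt1 and Mt2 lower. Socs3, a feedback inhibitor of cytokine signalling, had 1.93 ± 0.38 FPKM in water and 4.46 ± 0.60 in extract livers, and the protease inhibitor gene Serpina3m had 540 ± 87.4 and 961 ± 144. Kupffer markers, with a median of 0.56, and interferon-response genes, with 0.97, moved the same way. The serum amyloid gene Saa1 had 29.5 ± 6.32 and 96.7 ± 69.0 FPKM (limma adjusted p = 0.383). The median was 0.19 without extract 1 and 0.28 after quantile normalization, and the count over the list alone was 4 without water 2 and 3 without extract 1 or extract 2. That count of 10 was 5 after median centring or median-of-ratios scaling, 6 after quantile normalization or without the 20 highest genes, 4 with no filter on low genes and 17 with library weights.

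4 further lists were called higher with small medians. Inflammatory signalling had a median of 0.22 over 15 members (camera adjusted p = 0.00796; adjusted p = 0.396 with an estimated correlation), with Tlr2, which macrophages also express, at 0.57 ± 0.12 and 1.14 ± 0.20 FPKM, and 0 members passed limma over the list alone (3 at unadjusted p below 0.05). Tlr2 reached 1 FPKM only in the extract libraries, so it was tested only because it was higher there. Kupffer cell markers were higher by more in the same comparison (median 0.56). Stress genes of the endoplasmic reticulum and amino acid response had a median of 0.24 over 29 members (camera adjusted p = 0.0108; adjusted p = 0.524 with an estimated correlation). Over that list alone 5 were higher and 1, Gdf15, lower; the chaperone gene Calr had 159 ± 37.0 and 269 ± 29.8 FPKM and Sdf2l1 had 2.69 ± 0.48 and 6.27 ± 1.07. Immediate early genes had a median of 0.36 over 20 members (camera adjusted p = 0.00595; adjusted p = 0.53 with an estimated correlation), with Ier2 and Zfp36 past the threshold over the list alone. Proteasome genes had a median of 0.14 over 31 members (camera adjusted p = 0.00339; adjusted p = 0.60 with an estimated correlation), and 0 passed limma over the list alone (1 at unadjusted p below 0.05). In these 4 lists no member passed limma over all genes (at unadjusted p below 0.05, 10 stress and 6 immediate early genes did).

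Single libraries ended several of these calls. Without water 3 the camera adjusted p was 0.0711 for inflammatory signalling, 0.0711 for immediate early genes and 0.36 for the proteasome list, whose median was then 0.08 (0.25 without water 1, 0.09 without the 20 highest genes, 0.22 with library weights). Without extract 1 it was 0.0765 for inflammatory signalling, 0.0608 for immediate early genes and 0.0502 for the stress list, which was also lost without water 2 (0.0889, median 0.14). The stress median was 0.37 without water 1 and 0.14 without extract 2, and its count over the list alone was 11 without water 1, 3 without water 2, and 2 without water 3 or extract 2. It was 0 with a filter at a mean of 5 FPKM, 2 after median centring, 3 after the other scalings or without the 20 highest genes, and 13 with library weights. For immediate early genes that count was 8 without water 1, 4 without water 2 or extract 2, and 0 without water 3, extract 1 or extract 3, and the median was 0.61 with a filter at a mean of 5 FPKM. The immediate early count was 0 after median centring, after median-of-ratios scaling or with no filter, 1 with either smaller pseudocount and 8 with library weights. The inflammatory median was 0.15 with no filter on low genes, and 2 inflammatory genes passed over the list alone with library weights.

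Genes of gluconeogenesis and the fasting response were called lower as a list, with 17 of 21 fold changes negative and a median of -0.21 (camera adjusted p = 2.26e-05; adjusted p = 0.396 with an estimated correlation). So were amino acid catabolism and urea cycle genes, with 33 of 43 negative and a median of -0.21 (camera adjusted p = 6.85e-06; adjusted p = 0.396 with an estimated correlation). The aspartate aminotransferase gene Got1, a member of both, had 227 ± 67.4 FPKM in water and 76.0 ± 16.9 in extract livers. Nnmt had 16.4 ± 11.3 and 1.63 ± 0.61, Fbp1 had 988 ± 73.8 and 689 ± 59.6, Oat had 199 ± 48.8 and 97.3 ± 15.1, and the urea cycle gene Asl had 448 ± 97.1 and 242 ± 34.1. None passed limma over all genes (4 gluconeogenic and 11 amino acid genes at unadjusted p below 0.05). Over the list alone 4 gluconeogenic genes were lower (2 without extract 2 or with no filter on low genes), and of the amino acid genes 3 were lower and Kynu higher. That count of 4 was 1 without any one of water 1, water 2, extract 1 or extract 2 and 8 without extract 3, 8 after quantile normalization and 14 with library weights, and the amino acid median was -0.14 without water 2 and -0.13 without extract 1.

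Oxidative phosphorylation genes were called lower as a list, with 53 of 55 fold changes negative and a median of -0.16 (camera adjusted p = 5.82e-07; adjusted p = 0.541 with an estimated correlation). By limma 0 members passed over all genes or over the list alone, and 1, Ndufb8, had an unadjusted p below 0.05 (209 ± 41.9 against 157 ± 16 FPKM). That call rested on water 1: without it the median was -0.02 (camera adjusted p = 0.121), and with library weights it was -0.05.

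Periportal hepatocyte genes had a median of -0.14 over 26 members (camera adjusted p = 0.0281; adjusted p = 0.541 with an estimated correlation), although Cdh1, the cell adhesion gene for E-cadherin, had 2.49 ± 0.75 FPKM in water and 6.05 ± 0.84 in extract livers. Targets of the drug-sensing receptors CAR and PXR had a median of -0.09 over 36 members (camera adjusted p = 0.00943; adjusted p = 0.551 with an estimated correlation). The mean of that list was -0.46. It shares Cyp2a4 (log2 fold change -3.2) and several Cyp2b, Cyp3a and Sult genes with the female-biased list, itself called lower. How far the shared genes carry the call was not tested. Por, the reductase that supplies electrons to cytochromes P450, had 453 ± 63.1 and 294 ± 30.4 FPKM. Bile acid genes had a median of 0.12 over 34 members (camera adjusted p = 0.0468; adjusted p = 0.524 with an estimated correlation), with Hsd3b7 at 73.9 ± 2.08 and 121 ± 6.11 FPKM, Akr1c6 at 369 ± 31.7 and 592 ± 69.5, and the transporter Slc51b at 0.38 ± 0.11 and 1.48 ± 0.31. Slc51b reached 1 FPKM only in the extract libraries, so it was tested only because it was higher there. Over all genes 0 members of these 3 lists passed limma's test (at unadjusted p below 0.05, 4 periportal genes were higher and 7 lower, 3 CAR and PXR targets higher and 10 lower, and 9 bile acid genes higher and 3 lower). Over the list alone 1 periportal gene was higher and 4 lower, 1 CAR and PXR target was higher and 2 lower, and 7 bile acid genes were higher and 1 lower.

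The direction of the periportal list turned to 0.03 without water 2 (camera adjusted p = 0.426) and that of the CAR and PXR list to 0.10 without extract 2 (0.467). The periportal call was also lost without extract 2 (0.0888) or extract 3 (0.0609) and after median centring (0.0754), quantile normalization (0.121) or no filter on low genes (0.0545), and its median was -0.25 without water 1 and -0.27 with library weights. The CAR and PXR call was also lost without water 1 (0.0604), after median centring (0.0585) or quantile normalization (0.094), with a filter at a mean of 5 FPKM (0.0518) and with library weights (0.114). Its median was -0.15 without water 1, -0.18 without water 2, -0.29 without extract 3, -0.20 with library weights and -0.15 without the 20 highest genes. The bile acid call was lost without water 1 (0.325), extract 1 (0.284), extract 2 (0.0595) or extract 3 (0.31), with no filter on low genes (0.0545), a filter at a mean of 5 FPKM (0.19) or library weights (0.144). Its median was 0.07 without water 1, 0.19 without water 3 and 0.08 after median centring. The periportal count over the list alone was 2 without water 2 or extract 2, 3 without extract 1 or with either other filter, and 11 with library weights. The CAR and PXR count was 1 without water 2 or water 3, 7 without extract 1 and 6 with library weights, and the bile acid count was 3 without water 2 or extract 1, 5 without water 3 and 12 with library weights.

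The other 19 tested lists were not called with the main settings. Targets of the aryl hydrocarbon receptor had a median of 0.20 (camera adjusted p = 0.139), NRF2 targets 0.08 (0.947), conjugation enzymes -0.09 (0.0568), glycolysis and glycogen -0.04 (0.11), the circadian clock -0.07 (0.472), heat shock 0.03 (0.986), p53 targets 0.02 (0.698), the cell cycle -0.11 (0.248), iron and haem 0.05 (0.717), retinoid metabolism 0.05 (0.702) and lipoproteins 0.05 (0.143). Cytosolic ribosomal proteins had a median of 0.10 (0.164), pericentral hepatocyte genes -0.02 (0.0892), stellate cells and fibroblasts 0.07 (0.698), neutrophils and monocytes 0.05 (0.717), MHC class II and dendritic cells 0.19 (0.139), erythroid cells -0.996 (0.0976) and adipocytes -0.05 (0.702), besides the hepatocyte list. Camera's direction was opposite to the median for NRF2 targets, heat shock, p53 targets and lipoproteins, and the adipocyte mean was positive while its median and camera's direction were negative. The mean had camera's sign for p53 targets (-0.03) and lipoproteins (-0.07), and the median's for heat shock (0.12) and NRF2 targets (0.0051). Adh4 was the 1 retinoid gene past the threshold over all genes, while Rdh16 had 50.0 ± 5.09 FPKM in water and 29.6 ± 3.85 in extract livers. 9 of these lists passed camera's threshold under some other setting. Ribosomal proteins passed as higher without water 1 (median 0.34, adjusted p = 4.28e-20), after quantile normalization (5.81e-05) and with library weights (5e-08), and as lower without water 3 (median -0.07, 0.0295). Targets of the aryl hydrocarbon receptor passed without water 1 (median 0.41, 0.00265) and with library weights (0.0239), and MHC class II genes without water 3 (0.0295) and with no filter on low genes (0.03). Passing as lower were conjugation enzymes without water 2 (0.0444), water 3 (0.041), extract 1 (0.00899) or extract 3 (0.0282), glycolysis without water 3 (0.0295), heat shock without extract 2 (median -0.10, 0.0372) and the cell cycle without water 2 (0.02) or with no filter (2.14e-06). Pericentral genes did so without water 2 (0.00765) or extract 3 (0.0364), and erythroid genes without water 3 (0.00221), with no filter (0.03) and with a filter at a mean of 5 FPKM (0.0172). The erythroid list holds Hbb-bs and Hbb-bt, both at 0 FPKM in water 3, so leaving out that library raised their water means. How far they carry that call was not tested. In the main test 3 of its 8 members were higher, among them Alas2 (23.9 ± 11.9 against 42.8 ± 19.3 FPKM). The hepatocyte median was -0.08 after quantile normalization and -0.09 without the 20 highest genes.

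Lists for cholangiocytes, T and NK cells, B cells, pancreas, muscle and mesothelium had fewer than 5 tested members.

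Of the genes chosen in advance 12 are given here, and none of these passed limma's threshold. Cyp1a1, the classical target of the aryl hydrocarbon receptor, was too low to test, with 0.33 ± 0.06 FPKM in water and 0.45 ± 0.13 in extract livers. Gclc, which encodes the catalytic subunit for glutathione synthesis, had 68.6 ± 4.31 and 100.0 ± 5.32 FPKM (limma adjusted p = 0.171), while Nqo1 had 3.98 ± 0.97 and 3.28 ± 1.0 and Hmox1 14.3 ± 1.06 and 15.1 ± 1.29. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 77.9 ± 50.9 and 35.2 ± 19.1 FPKM (limma adjusted p = 0.498), and the iron hormone gene Hamp 1973 ± 570 and 1291 ± 142 (limma adjusted p = 0.413). Cyp2b10 had 24.1 ± 6.53 and 11 ± 6.87 FPKM, Cyp3a11 4285 ± 937 and 5629 ± 1980, and Cyp1a2 373 ± 101 and 424 ± 79.3. Fasn had a limma adjusted p of 0.853.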

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

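Median-of-ratios, upper-quartile and common-sum scaling and library weights, and the list test under the other gene settings, were chosen after seeing the data; the rest were planned. Count-based tests, factors and thresholds were not run, since the values were FPKM. Of 5 genes called, 0 passed limma after median centring, with no filter on low genes (1566 genes at unadjusted p below 0.05), with treat against a 1.2-fold change (335), or with median-of-ratios factors. 2 passed after quantile normalization and with a pseudocount of 0.1 or 0.01, both lying among the 5. 33 passed at an adjusted p below 0.1 and 133 with library weights, all 5 included in each. Leaving out single libraries gave 0 to 48 genes. The lost calls came with little change in size: over 23 alternatives the log2 fold change of Hsd3b2 lay between 1.96 and 2.29 (adjusted p 0.00619 to 0.184), of Adh4 between 1.14 and 1.38 (0.0114 to 0.251), of Mt2 between -2.11 and -1.83 (0.0114 to 0.19), of Cyp4a10 between -1.51 and -1.31 (0.0238 to 0.221) and of Tm7sf2 between -1.22 and -1.07 (0.0114 to 0.221). With no filter, more genes were tested. Treat asked for a larger change, and leaving out a library left fewer from which to estimate the spread. How far these account for the losses was not tested, nor was the cause under the other settings.

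Of 19 lists called, 0 were called with an estimated correlation (3 of 38 at unadjusted p below 0.05) and 0 by fry's directional test (7 of 38), while its test for change in either direction passed for 14 of the 19; other alternatives called 16 to 21. Over 94 named genes and their alternatives, 1995 values kept their direction and side of the threshold, 63 lost and 80 gained a call, and 2 reversed, neither of them called: the log2 fold change of Cyp3a11 (-0.0813 after quantile normalization) and the log2 fold change of Hmox1 (-0.00482 with library weights). For the called lists these numbers were 351, 64, 0 and 2, the reversals being CAR and PXR targets (between -0.29 and 0.10 as single libraries were left out) and periportal genes (between -0.25 and 0.0332). No scaling moved the median of all genes by over 0.1. Unknown depth leaves the counting error of low genes open.

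Replicate numbers did not pair the libraries: correlations of same-numbered libraries' deviations were -0.017, -0.177 and 0.117, and only the libraries numbered 3 correlated best with each other. With the replicate number as a block, limma called 0 genes (922 at unadjusted p below 0.05) and camera 21 lists, 18 of them among the 19. The bile acid call was lost (adjusted p = 0.0746), and conjugation enzymes (0.0319), pericentral (0.0492) and erythroid genes (0.0207) were gained. Counts over the list alone were then 13 for bile acid, 8 for CAR and PXR, 8 for female-biased, 7 for immediate early, 2 for stress, gluconeogenic and periportal and 1 for amino acid genes.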

Other observations

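The comparisons added in this part were chosen only after the results were seen, as were the genes singled out here. The camera calls and limma p-values repeated here come from the planned tests. Hbb-bs, a beta-globin gene, had 338, 534 and 0 FPKM in the water libraries and 135, 1.95 and 0.90 in the extract libraries, and Hbb-bt followed it at lower levels. Hamp2, a paralog of the iron hormone gene, had 2.26, 914 and 479 FPKM in the water libraries and 125, 190 and 128 in the extract libraries. Irf9 had 56.2 FPKM in water 2 and 96.9 in extract 2, against 11.2 to 22.5 in the other libraries. Among tested genes, 11 varied by over 4 log2 units between water libraries and 10 between extract libraries, among them Cyp3a41a, Mup1 and Ren1 in water and Mup7, Mup15 and Cyp2b13 in extract; Sult2a2, Hbb-bt and Hbb-bs did so in both groups. Where Hbb-bs was below 5 FPKM, Hbb-b1 was still at 269 FPKM or more, so less blood does not account for the missing Hbb-bs; different beta-globin variants in these outbred mice are a candidate explanation.

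Clock genes were not called as a list, and its members differed in sign. Nr1d1, a repressor of the clock, had a log2 fold change of 1.21 and Dbp 0.44, while Nfil3, of the opposite phase, had -0.83. None of these 3 passed limma's threshold. Among abundant transcripts, Serpina1c had 2519 ± 263 FPKM in water and 4738 ± 853 in extract livers and Serpina3k 2968 ± 811 and 6389 ± 1396, neither past the threshold (limma adjusted p 0.173 and 0.201).

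The gene and list counts can be set beside other splits of the 6 libraries into 3 and 3, of which there are 10, too few for a share under 0.05. As many genes as the 5 of the real split came from 3 splits, the real one included, with 7 genes in the highest other split. At unadjusted p below 0.05 the real split gave 1061 genes and the highest other 1060, the one that exchanged water 1 and extract 3. For the 19 lists it was 1 split, the real one, with 17 lists in the highest other. List scores without overlap numbered 9 in the real split and 7 in the highest other. The split that exchanged water 1 and extract 3 gave 5 such scores and 1 called gene.

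The interferon list was called higher by camera with the preset correlation but not without it (adjusted p = 0.396 with an estimated correlation), with scores of 3.92 and 4.20 in extract 1 and extract 2 and 2.84 in extract 3. A lower share of hepatocytes alone would raise Kupffer and endothelial markers alike. The Kupffer and endothelial scores differed by 0.53 and -0.16 (extract minus water, log2 scale), results already seen. The Kupffer score minus the endothelial score was 0.689 higher in extract livers (no overlap between groups, exact permutation p = 0.1, the smallest possible). This argues against a lower hepatocyte share as the only cause, but not against it beside changes in either cell type. More Kupffer cells may carry part of the signal. The interferon score minus the Kupffer score was 0.484 higher in extract livers, but the groups overlapped (exact permutation p = 0.4), so this cannot be told apart from induction within cells. An effect of the extract itself stays open, as untested.

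Male-biased genes were called higher and female-biased genes lower by camera with the preset correlation but not without it (adjusted p = 0.396 for each with an estimated correlation), and the female-biased scores overlapped (exact permutation p = 0.2). A library made only from female mice is excluded, since the lowest sum of 4 Y-linked genes in any library was 25.1 FPKM. Female tissue mixed with male tissue in a library is not, since no female-specific transcript was examined. Genes without a near-identical copy argue against reads shared between copies as the whole cause. The 9 male-biased ones were 0.754 higher on average (log2 scale, no overlap, exact permutation p = 0.1, the smallest possible). The female-biased ones differed by -0.762 (no overlap, exact permutation p = 0.1). Both sets came from lists whose results had been seen. The summed major urinary protein genes had 5131 ± 3870 FPKM in water and 28529 ± 18627 in extract livers, with 7461 in extract 3 and 9582 in water 1. An effect of the extract stays open, as untested.

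Fatty acid oxidation and synthesis genes were both called lower by camera with the preset correlation but not without it (adjusted p = 0.396 for each with an estimated correlation), although feeding and fasting would move them in opposite directions. The synthesis score differed by -0.434 (extract minus water), but its groups overlapped (exact permutation p = 0.3), so fed against fasted animals cannot be told apart from other causes. A different clock time at sampling cannot be told apart from other causes either. The mean of the Nr1d1 arm (10 genes) minus that of Clock, Cry1 and Nfil3 was 0.587 higher in extract livers, with no overlap (exact permutation p = 0.1), but these arms were set after Nr1d1 and Nfil3 had been seen, and 5 of the 10 genes (Tef, Hlf, Ciart, Per2 and Usp2) had fold changes below 0. The labels give no time of killing, and an effect of the extract stays open, as untested.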
